A study of Mus musculus with 4 samples.

How the data were processed

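Mononuclear cells were isolated from quadriceps and diaphragm of WT and mdx5cv mice aged 14 weeks, cryopreserved and profiled with the 10x Genomics 3' v3.1 chemistry, which counts tags at the 3' end of transcripts, for a target of 5000 cells per library. The 4 libraries were each 1 group, and the labels do not say how many animals or which animals gave each. The deposited matrices are unfiltered and hold 1 UMI count per gene and barcode, for 32285 genes. Per the submitters' processing notes they were made with Cell Ranger 5.0.0 on mm10, whereas the matrix header names Cell Ranger 4; the annotation is not given in the sources used here. GENCODE M21 (GRCm38, the assembly also called mm10) was used for positions, which are 1-based, and 32158 of the 32285 gene identifiers (99.6%) were found in it.

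The computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. Barcodes with at least 1000 UMIs and 500 genes were taken, 5546 (WT quadriceps), 7831 (WT diaphragm), 9010 (mdx5cv quadriceps) and 7750 (mdx5cv diaphragm). Those above 15% mitochondrial UMIs, 635, 315, 676 and 348, were left out. Scrublet, as built into scanpy, then called 2 of 4911, 0 of 7516, 300 of 8334 and 343 of 7402 barcodes doublets. Its automatic threshold therefore did not work in the WT libraries and acted unevenly between genotypes, which is why removing the highest scores in every library (193, 452, 556 and 438 barcodes) was added as an alternative. Counts were scaled to 10000 per cell and log-transformed, and the 4 libraries were clustered together on 2000 variable genes and 30 principal components, with 15 neighbours and Leiden resolution 1.0, which gave 38 clusters.

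Of 20 classes with marker lists, 15 were named. A cluster took the class whose markers had the highest mean excess over the other clusters, if at least 3 markers were detected in over 10% of its cells and stood above the other clusters. The rule that dropped a name for sharing its top 10 genes with another class was relaxed after the clusters had been seen, because the strict form left 3 FAP-like clusters and 1 macrophage-like cluster unnamed by 1 marker each. As applied, it dropped a name if the top 10 genes against clusters of other classes held more markers of another class than its own. A name was also dropped if the top 10 against all clusters held at least 2 more. So was that of a cluster with a low UMI count for its library and no own marker in either top 10. The strict form was kept as an alternative. Unnamed cells numbered 97, 102, 12 and 33, in the library order above. Classes are called FAP-like and so on because they rest on transcripts alone.

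UMIs were summed per class and library and divided by the class total. Ratios of CPM have exact conditional 95% intervals. In lists a count under 3 was set to 3. A single gene with 0 UMIs on 1 side is given with that side set to 3, written as at the floor, and one with 1 or 2 UMIs as counted. A value at the floor is not a confidence limit, since it leaves out counting error. A list median covers members with at least 5 CPM in 1 of the 2 libraries and has an order-statistic interval across members. It was set against 10000 random lists matched in size and in 20 expression bins. A member was called higher or lower at 1.5-fold or more with an interval excluding 1. The genotype by muscle difference has a delta-method interval. The ambient share was estimated from markers of other classes against barcodes with 10 to 100 UMIs.

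The 32 gene lists, the comparisons, the named-gene rule and the alternatives, apart from those named below as chosen later, were written before the data were examined. Named genes had at least 20 CPM in the higher library of both parallel comparisons and the same direction with both intervals excluding 1. They were ranked by the smaller of the bounds nearest 1, taking the 12 highest and 10 lowest for FAP-like genotype and muscle, 8 and 8 for macrophage-like and endothelial-like genotype, and 6 and 6 for the genotype by muscle difference. Of the last, 1 gene is not reported here. Mitochondrial, ribosomal, haemoglobin, predicted, Riken, Xist and Y-linked genes were left out, as were genes with over 20% estimated ambient origin. List members were named where called the same way in both comparisons, and genes of muscle stem cell-like cells through the lists only. Col1a1, Col3a1, Dmd and Utrn were given whatever their values. Genes that went opposite ways and members with values in 1 muscle were chosen after their values were seen.

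Recovery was tested on simulated data drawn as Poisson counts from the pooled WT and mdx5cv FAP-like profile of each muscle at the real depths, a change counting as recovered when its interval excluded 1. In quadriceps (10518 genes) 84% of 1.5-fold increases, 72% of 1.5-fold decreases, 100% of 2-fold increases and 94% of 2-fold decreases were recovered. In diaphragm (9961 genes) 100% and 96% of 1.5-fold changes and 100% of 2-fold changes were. The intervals of unchanged genes covered their value in 95.6% and 95.3% of cases, for counting error alone. The alternatives were minimums of 500 UMIs and 300 genes or 2000 UMIs and 1000 genes, a mitochondrial limit of 5%, doublets kept, Leiden resolutions of 0.5 and 2.0, components centred per library, median-ratio and per-cell scaling, cells thinned to 1500 UMIs, ambient subtraction, no or a 50 CPM minimum, and 4 subcluster settings. Chosen after seeing the data were the removal of the highest doublet scores, the strict naming, low-stress FAP-like cells and FAP-like cells without macrophage-marker UMIs.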

Results

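Single-cell RNA sequencing was performed on mononuclear cells from the quadriceps and the diaphragm of wild-type (WT) mice and of mdx5cv mice, a dystrophin-mutant model of Duchenne muscular dystrophy, at 14 weeks of age. The series concerns fibro/adipogenic progenitors (FAPs), the resident mesenchymal cells of skeletal muscle, in muscle fibrosis. There was 1 library for each muscle and genotype, 4 in all, so no difference below has a replicate check and no p-value was computed. The libraries held 18837891 (WT quadriceps), 40226833 (WT diaphragm), 62780685 (mdx5cv quadriceps) and 49612759 (mdx5cv diaphragm) unique molecular identifiers (UMIs). After filtering, 4909, 7516, 8034 and 7059 cells remained in the same order, with median depths of 2055, 4355.5, 5328.5 and 4894.5 UMIs before doublet removal. Each ratio is of CPM, UMIs summed over the cells of a class and scaled to a common class total, with its exact 95% counting interval in parentheses. These intervals, like the exact binomial intervals of shares, cover counting error only and leave out variation between animals and preparations. Intervals of ratios and of shares of UMIs also leave out variation between cells, since UMIs were summed over the cells of a class.

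Immune cells made up most of the mononuclear cells recovered from mdx5cv quadriceps. Among those recovered from mdx5cv diaphragm they were close to as many as all other classes. Immune classes together held 9.37% (8.57 to 10.2) of cells in WT quadriceps and 70.0% (69.0 to 71.0) in mdx5cv quadriceps. In diaphragm they held 11.8% (11.1 to 12.6) in WT and 47.9% (46.8 to 49.1) in mdx5cv. Macrophage-like cells, which clear debris and signal to repairing muscle, were the largest immune class in both mdx5cv libraries. They made up 5.05% (4.46 to 5.70) of WT and 43.5% (42.4 to 44.6) of mdx5cv quadriceps cells, and 2.41% (2.07 to 2.78) of WT and 21.9% (21.0 to 22.9) of mdx5cv diaphragm cells. Monocyte-like cells, their blood-borne precursors, were 0.917% (0.669 to 1.22) and 11.7% (11.0 to 12.4) in quadriceps, and 0.412% (0.280 to 0.585) and 5.41% (4.90 to 5.97) in diaphragm. Dendritic-like cells were 2.28% and 10.2% in quadriceps, and 0.625% and 7.10% in diaphragm. B-like cells were more frequent in diaphragm, at 3.13% in WT and 6.83% in mdx5cv, than in quadriceps, at 0.265% and 0.124%. T-like cells were 0.346%, 2.08%, 3.26% and 4.84% of WT quadriceps, WT diaphragm, mdx5cv quadriceps and mdx5cv diaphragm cells, and type 2 innate lymphoid-like cells 0.428%, 3.02%, 0.585% and 1.61%. Neutrophil-like cells stayed at or below 0.660% of each library.

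FAP-like cells made up 17.8% (16.7 to 18.9) of WT and 18.4% (17.5 to 19.2) of mdx5cv quadriceps cells, against 81.7% (80.8 to 82.5) of WT and 41.8% (40.6 to 43.0) of mdx5cv diaphragm cells. Among non-immune cells alone the FAP-like share was 19.6% (18.5 to 20.8) in WT and 61.2% (59.2 to 63.2) in mdx5cv quadriceps, and 92.6% (91.9 to 93.2) and 80.3% (78.9 to 81.5) in diaphragm. There were 0.284 macrophage-like cells per FAP-like cell in WT quadriceps, 2.37 in mdx5cv quadriceps, 0.0295 in WT diaphragm and 0.524 in mdx5cv diaphragm. Endothelial-like cells, which line vessels, were 54.7% (53.2 to 56.1) of WT quadriceps cells and 0.785% (0.598 to 1.01) of WT diaphragm cells, against 5.2% (4.73 to 5.71) and 4.79% (4.30 to 5.31) in the mdx5cv libraries. Muscle stem cell-like cells were 9.41% (8.61 to 10.3), 1.74% (1.46 to 2.06), 3.8% (3.39 to 4.24) and 3.53% (3.11 to 3.98) of WT quadriceps, WT diaphragm, mdx5cv quadriceps and mdx5cv diaphragm cells. Cells named tenocyte-like numbered 88 in WT and 119 in mdx5cv quadriceps and 2 and 7 in diaphragm, where the tenocyte marker Tnmd also led FAP-like cluster 4, with 1606 WT diaphragm cells, left unnamed by the stricter rule given below. FAP-like cluster 3, with 2128 mdx5cv diaphragm cells and the tenocyte marker Thbs4 among its top 10 genes, was also unnamed by that rule. Mesothelial-like cells were seen in the diaphragm libraries only, at 1.38% (1.13 to 1.67) and 0.765% (0.575 to 0.997). Their count of 0 in quadriceps has an exact interval of up to 0.0751% in WT and 0.0459% in mdx5cv. Shares may depend on how each tissue was dissociated and frozen, which was not tested. They depended on the UMI minimum, and the WT quadriceps library was the shallowest. In WT and mdx5cv quadriceps the FAP-like shares were 30.64% and 20.13% above 2000 UMIs, and 33.97% and 23.81% with a mitochondrial limit of 5%, so their near equality depended on the filter. They also depend on class naming, which was relaxed after the clusters had been seen: under a stricter rule FAP-like cells were 58.48% of WT and 5.766% of mdx5cv diaphragm cells.

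**Figure D1:**
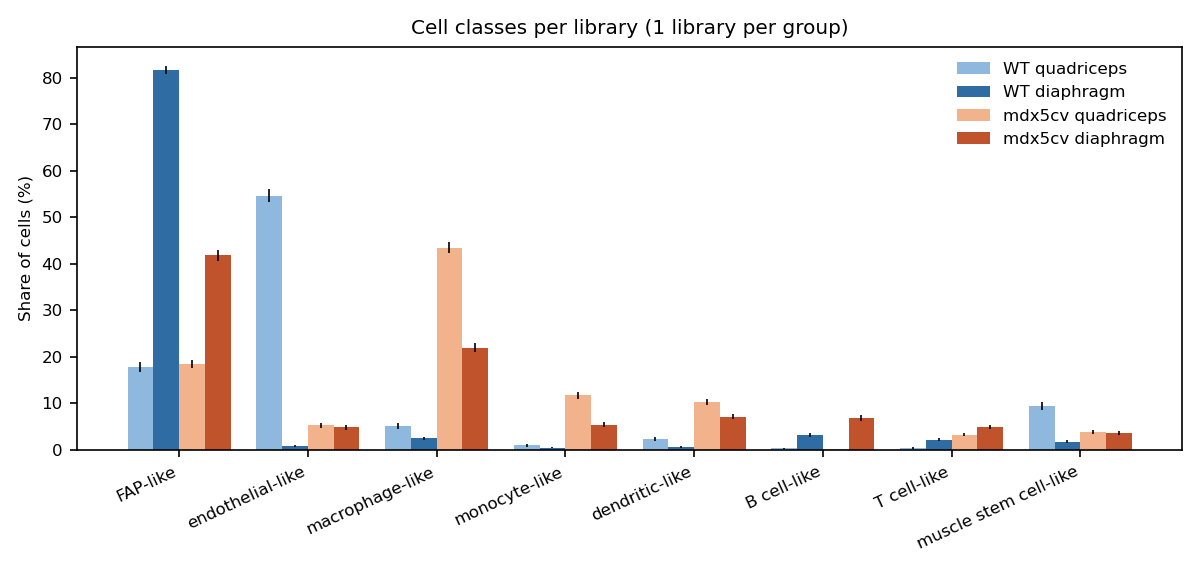
Share of cells (percent, linear axis from 0) in each cell class for the 4 libraries, 1 per muscle and genotype, with exact 95% binomial intervals as error bars. Macrophage-like cells took 43.5% of mdx5cv quadriceps and 5.05% of WT quadriceps cells, and FAP-like cells 81.7% of WT diaphragm cells.

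FAP-like cells of both mdx5cv libraries carried more fibrillar collagen transcript than those of the matching WT muscle. Col1a1, a chain of type I collagen, was 4.77-fold (4.66 to 4.88) higher in mdx5cv quadriceps and 3.93-fold (3.89 to 3.97) higher in mdx5cv diaphragm, at 2277 and 10851 CPM in WT and mdx5cv quadriceps and 1793 and 7038 CPM in diaphragm. Col3a1, the type III collagen chain, was 2.59-fold (2.56 to 2.63) and 2.94-fold (2.92 to 2.95) higher. Of the 14 fibrillar and associated collagens, 13 were at least 1.5-fold higher in mdx5cv quadriceps and 11 in mdx5cv diaphragm, with 0 lower in either, and 10 were higher in both. The list's median log2 ratio was 1.36 (0.73 to 2.25) in quadriceps and 1.20 (0.24 to 1.81) in diaphragm. Such an interval of a list median describes the spread among its members and not counting error. Each median stood at percentile 100 of 10000 random lists of the same size and expression, a description of these libraries and not a test. Genes that process and crosslink collagen were also higher, 10 of 16 in quadriceps and 7 of 16 in diaphragm with 0 lower in either (medians 1.0 and 0.57). They included the lysyl oxidase Lox, 3.44-fold (3.12 to 3.81) and 2.02-fold (1.95 to 2.10) higher, and the lysyl hydroxylase Plod2, 3.44-fold (2.94 to 4.04) and 2.18-fold (2.06 to 2.29) higher. Basement membrane genes showed no common direction, with medians of −0.04 (−0.83 to 0.39) and 0.03 (−0.37 to 0.52) over 15 genes, and Col4a5 alone was lower in both muscles. With only the clusters named under the stricter rule (866, 4395, 1252 and 407 FAP-like cells in WT quadriceps, WT diaphragm, mdx5cv quadriceps and mdx5cv diaphragm), the collagen medians were 1.40 and 1.15.

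**Figure D2:**
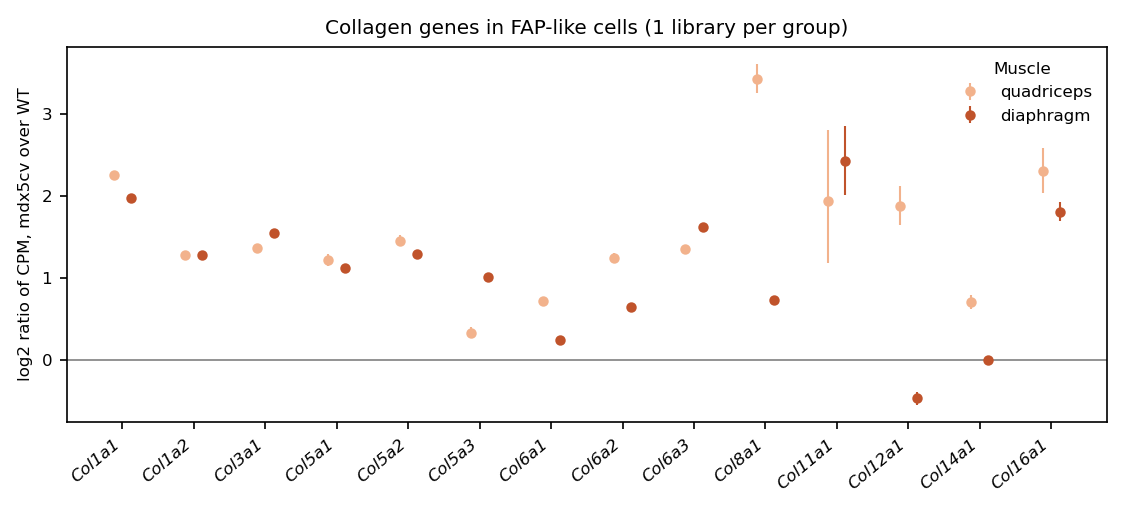
Log2 ratio of CPM, mdx5cv over WT, for each collagen gene in FAP-like cells, with quadriceps and diaphragm side by side and exact 95% counting intervals as error bars. Of 14 genes, 10 were at least 1.5-fold higher in both muscles, while Col12a1 was 3.68-fold higher in quadriceps and 1.38-fold lower in diaphragm.

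Several matrix genes were among the named genes with the largest ratios in mdx5cv FAP-like cells. Tnc, the injury-associated glycoprotein tenascin-C (chromosome 4, 63959785 to 64047015, GRCm38), was 55.3-fold (40.5 to 77.4) higher in mdx5cv quadriceps and 63.9-fold (54.8 to 74.9) higher in mdx5cv diaphragm. Postn, encoding periostin (chromosome 3, 54361109 to 54391037), was 54.1-fold (47.4 to 62.1) and 13.3-fold (12.9 to 13.7) higher. Timp1, an inhibitor of matrix metalloproteinases, was 28.5-fold (23.6 to 34.7) and 19.5-fold (18.7 to 20.3) higher. Cthrc1, a secreted protein of activated fibroblasts, was 194-fold (75.9 to 714) higher in quadriceps, where WT held 4 UMIs, and 17.7-fold (15.7 to 20.1) higher in diaphragm. The metalloproteinase Adam12 was 175-fold (48.3 to 1446) higher in quadriceps, from 2 UMIs in WT, and 17.8-fold (14.8 to 21.6) in diaphragm. Ltbp2, of the latent TGF-beta binding family, was 46.9-fold (26.2 to 94.2) and 11.5-fold (10.2 to 12.9) higher, the prolyl hydroxylase subunit P4ha3 47.1-fold (20.1 to 146) and 12.6-fold (9.61 to 16.9), and the matricellular gene Ccn4 26.9-fold (16.0 to 49.3) and 15.3-fold (13.2 to 17.7). Comp, a cartilage and tendon matrix protein, was 10.0-fold (7.53 to 13.6) and 8.96-fold (7.75 to 10.4) higher. Slc7a2, an arginine transporter, was 12.3-fold (7.97 to 19.9) and 9.78-fold (8.26 to 11.6) higher. The sizes depended on the setting, since thinned cells weakened 12 of the 22 genes named for genotype in quadriceps by over 1.5 times. At their weakest across settings the quadriceps log2 ratios of Tnc, Cthrc1, Adam12 and Timp1 were 4.788, 5.968, 4.642 and 3.721. Of 27 matrix glycoproteins and proteoglycans, 15 were higher and 6 lower in quadriceps and 9 higher and 5 lower in diaphragm (medians 0.67 and 0.14). The small proteoglycan Dcn was lower in both muscles, 3.34-fold (3.31 to 3.37) and 1.63-fold (1.62 to 1.64), as were Tnxb, Ogn and the elastic fibre gene Fbln5. Fbln2 went opposite ways, 1.65-fold higher in quadriceps and 1.5-fold lower in diaphragm. Matrix proteases and inhibitors were divided, with 7 of 18 higher and 5 lower in quadriceps and 5 of 17 higher and 5 lower in diaphragm (medians 0.28 and 0.39). Mmp3 and Mmp14 were higher in both muscles and the plasminogen activator Plau and Timp3 lower in both.

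Contractile genes of myofibroblasts were higher in mdx5cv FAP-like cells. Acta2, smooth muscle actin, was 5.54-fold (4.42 to 7.02) and 4.62-fold (4.22 to 5.06) higher, and Tagln 9.36-fold (6.07 to 15.2) and 4.11-fold (3.54 to 4.78) higher. Of 7 such genes, 5 were higher in each muscle and 0 lower (medians 1.31 and 0.72). Ligands, receptors and targets of TGF-beta, the main profibrotic cytokine, were less uniform. In quadriceps 8 of 19 were higher and 2 lower (median 0.31, −0.19 to 1.33), and in diaphragm 5 were higher and 5 lower (median 0.02, −0.63 to 0.87). Tgfb3 was 3.37-fold (2.80 to 4.08) and 2.35-fold (2.24 to 2.47) higher, Ltbp1 and the receptor gene Tgfbr3 were lower in both muscles, and the target Ccn2 was 2.52-fold higher in quadriceps and 2.01-fold lower in diaphragm.

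Transcripts of the Pi16- and Dpp4-positive fibroblast state, held to be a progenitor-like reservoir, were lower in FAP-like cells of both mdx5cv libraries. Dpp4 was 9.68-fold (8.50 to 11.0) lower in quadriceps and 5.48-fold (4.81 to 6.26) lower in diaphragm, and Pi16 8.22-fold (7.83 to 8.62) and 3.34-fold (3.27 to 3.41) lower. Of the 15 genes of this list, 14 were lower in quadriceps and 13 in diaphragm, with 0 higher (medians −2.57, −3.16 to −1.71, and −1.57, −2.40 to −1.17; both at percentile 0). Ackr3, a scavenging receptor for Cxcl12, was 8.57-fold (7.85 to 9.37) and 8.24-fold (7.74 to 8.77) lower, and Efhd1 12.9-fold (11.1 to 15.1) and 7.34-fold (6.29 to 8.62). The procollagen enhancer Pcolce2 was 9.70-fold (9.0 to 10.5) and 6.76-fold (6.36 to 7.19) lower, the carboxylesterase Ces1d 14.5-fold (10.3 to 21.0) and 11.2-fold (9.51 to 13.2), and placental growth factor, Pgf, 10.6-fold (7.28 to 15.6) and 15.4-fold (12.2 to 19.7). Stmn4, the guidance cue Sema3d, the morphogen Bmp7 and the sulfotransferase Chst1 were between 7.26-fold and 24.6-fold lower. Genes of the Col15a1- and Smoc2-positive state had medians of −0.44 (−1.11 to 0.57) and 0.10 (−1.09 to 0.37), with Hsd11b1, which regenerates active glucocorticoid, 5.04-fold and 5.46-fold lower. Under the stricter naming the diaphragm median of the Pi16 and Dpp4 list was −0.60, the diaphragm log2 ratios of Efhd1, Bmp7, Chst1 and Pcolce2 were −0.871, −0.9014, −0.9172 and −1.334, and 11 of the 22 genes named for genotype were weaker there by over 1.5 times. Different clusters held most FAP-like cells of each library. Cluster 0 (C3, Ccl11, Ces1d) and cluster 4 (Sfrp4, Tnmd) held 3280 and 1606 of 6138 cells in WT diaphragm. Cluster 3 (Col6a5, Fbln7, Thbs4) held 2128 of 2950 in mdx5cv diaphragm, cluster 7 (Postn, Cxcl14, Mmp3) 924 of 1476 in mdx5cv quadriceps, and clusters 8 and 10 (Sema3c, Efhd1; Ccl11, Hsd11b1) 309 and 235 of 874 in WT quadriceps.

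Interferon-response genes were higher in mdx5cv FAP-like cells of both muscles. Isg15, an interferon-induced ubiquitin-like protein, was 4.42-fold (3.48 to 5.69) higher in quadriceps and 6.12-fold (5.51 to 6.82) in diaphragm, and the antiviral gene Rsad2 4.54-fold (2.47 to 9.25) and 8.13-fold (5.86 to 11.5). Of 20 genes, 13 were higher and 1 lower in quadriceps, 14 higher and 1 lower in diaphragm, and 13 higher in both (medians 0.85, 0.25 to 1.15, and 1.08, 0.47 to 1.74). The peptide transporter Tap1 was 2.97-fold and 2.64-fold higher, within an MHC class I list of medians 0.33 and 0.19. Chemokines and cytokines were divided. Cxcl9, an interferon-gamma target that draws T cells, was 14.5-fold (9.50 to 23.2) and 57.0-fold (41.3 to 80.9) higher, Cxcl5 66.7-fold (22.7 to 324) and 14.8-fold (10.8 to 20.9), and the monocyte attractant Ccl2 6.72-fold (5.99 to 7.56) and 2.09-fold (2.03 to 2.15). The eosinophil attractant Ccl11 was 5.57-fold (5.34 to 5.80) and 10.5-fold (9.84 to 11.1) lower. In all 8 of 20 were higher in each muscle, and 5 lower in quadriceps and 7 in diaphragm (medians 0.47 and −0.02). Complement genes were more often lower, 6 of 12 in quadriceps and 5 of 11 in diaphragm, including C3, 2.48-fold and 1.66-fold lower, while Cfb was 2.04-fold and 1.96-fold higher (medians −0.48 and −0.56). Il1rl1, the receptor for Il33, was 113-fold (61.0 to 236) higher in diaphragm and 42.7-fold (11.7 to 354) higher in quadriceps, where WT held 2 UMIs. At weakest across settings its log2 ratio was 3.724 in diaphragm and 2.362 in quadriceps.

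Among trophic and morphogen factors, 6 of 25 were higher and 10 lower in quadriceps, 6 of 24 higher and 5 lower in diaphragm, and 6 higher and 3 lower in both muscles. Those higher in both included Spp1, 6.14-fold (4.58 to 8.40) and 17.2-fold (10.1 to 31.5), and the muscle stem cell mitogen Hgf, 7.97-fold (3.8 to 20.1) and 3.90-fold (3.01 to 5.10). Vegfa was 3.31-fold (2.80 to 3.91) and 3.33-fold (2.99 to 3.72) lower, and the list's medians were −0.08 and −0.23. Adipogenic and lipid genes had medians of −0.46 (−0.83 to 0.98) and 0.00 (−1.34 to 1.90). In that list the preadipocyte factor Dlk1 was 3.41-fold (2.45 to 4.88) and 6.62-fold (5.83 to 7.54) higher, and Fabp4 was 3.82-fold lower in quadriceps and 4.77-fold higher in diaphragm. Fabp4 also led a FAP-like subcluster with endothelial genes. The endothelial-like share moved the same way, from 54.7% to 5.2% in quadriceps and from 0.785% to 4.79% in diaphragm. Spp1 was also higher in macrophage-like cells of both mdx5cv libraries, which held more such cells per FAP-like cell than the matching WT libraries. List members were not filtered for ambient origin. Whether Fabp4 came from endothelial RNA, or Spp1 from macrophage RNA, was not tested. Cell cycle genes were higher in mdx5cv quadriceps, 14 of 14 (median 3.68, 2.52 to 4.72, with 2 genes set at the floor of 3 counts), and 3 of 9 in diaphragm (median 0.42, 0.02 to 0.69). The diaphragm median depended on the setting, from −0.5234 with the highest doublet scores removed and −0.4816 among low-stress cells to 2.51 under the stricter naming and 3.057 with principal components centred per library, and the quadriceps median was 1.995 with thinned cells. Genes of arrest and damage had medians of −0.02 and −0.01, with Cdkn1a, a cell cycle inhibitor, 1.78-fold and 2.41-fold lower. Immediate-early and dissociation stress genes were lower, 9 of 17 in quadriceps (median −0.59, −0.85 to −0.08) and 16 of 17 in diaphragm (median −2.10, −2.62 to −1.65). Positional genes of the hindlimb and trunk lists had quadriceps medians of 0.12 and 0.07 and diaphragm medians of 1.05 (2 genes) and −0.17. RNA of other cells was present: the estimated ambient share of FAP-like UMIs was 6.67%, 3.41%, 14.4% and 5.61% in WT quadriceps, WT diaphragm, mdx5cv quadriceps and mdx5cv diaphragm, and 168 of 1476 mdx5cv quadriceps FAP-like cells carried 3 or more macrophage-marker UMIs against 6 of 874 in WT.

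Dmd, the gene mutated in mdx5cv mice (chromosome X, 82948870 to 85206141, GRCm38), was 1.44-fold (1.16 to 1.78) lower in mdx5cv quadriceps and 1.24-fold (1.12 to 1.37) lower in mdx5cv diaphragm FAP-like cells. A 3' tag count does not read the mutation, so these values do not check the genotype labels. Its homologue Utrn was 1.66-fold (1.45 to 1.89) lower in quadriceps and 1.07-fold (0.989 to 1.17) higher in diaphragm. Sgcd was lower in FAP-like cells of both muscles. The dystrophin complex list had medians of −0.53 and −0.23 in FAP-like and 0.18 and −0.24 in macrophage-like cells. Its medians were 0.17 and −0.37 in endothelial-like and 0.33 and 0.01 in muscle stem cell-like cells. In muscle stem cell-like cells 8 members were measured in both muscles, of which Dmd was called lower and Dtna higher in both. The Y-linked genes, which would show a library from animals of the other sex, had FAP-like medians of −0.06 (−0.96 to 0.14) and −0.03 (−0.40 to 0.43).

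**Figure D3:**
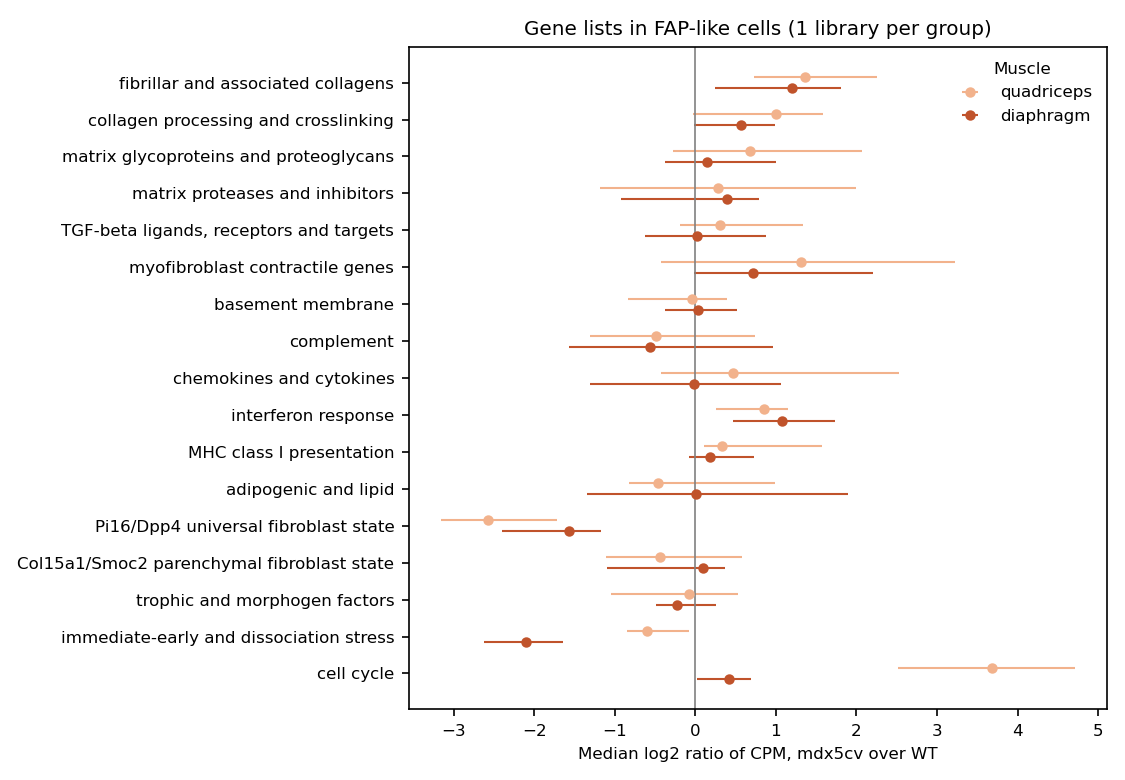
Median log2 ratio of CPM, mdx5cv over WT, of each gene list in FAP-like cells (horizontal axis), with quadriceps and diaphragm as separate points and order-statistic intervals across list members as error bars. Collagens lay at 1.36 and 1.20 and the Pi16 and Dpp4 list at −2.57 and −1.57.

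Diaphragm and quadriceps FAP-like cells were told apart first by positional transcription factors, in WT and in mdx5cv alike. Hoxc10, a posterior Hox gene (chromosome 15, 102966796 to 102971893), had 229 and 984 UMIs in WT and mdx5cv quadriceps and 0 in either diaphragm library. It was 705-fold and 513-fold lower there with 0 set at the floor of 3 counts, which gives no confidence limit. Hoxa10 was 422-fold and 170-fold lower in diaphragm, also at the floor. The limb gene Tbx15 was 60.2-fold (37.9 to 100.4) and 48.8-fold (30.6 to 83.0) lower, and Shox2 33.1-fold (23.8 to 47.0) and 27.2-fold (19.5 to 39.3) lower. Wt1, which acts in the mesenchyme that forms the diaphragm (chromosome 2, 105126529 to 105173616), had 2328 UMIs in WT diaphragm and 0 in WT quadriceps, 84.0-fold higher at the floor. In mdx5cv diaphragm it was 230-fold (63.5 to 1904) higher than in mdx5cv quadriceps, which held 2 UMIs. Gata4 was 27.4-fold and 78.0-fold higher in diaphragm, at the floor. Gata6 was 12.3-fold (6.87 to 24.8) and 8.0-fold (6.17 to 10.5) higher there, and Hoxb4 12.7-fold (5.83 to 34.8) and 5.30-fold (3.91 to 7.34). Of the hindlimb list, 5 of 6 measured genes were lower in WT diaphragm and 6 of 8 in mdx5cv diaphragm (medians −7.80 and −6.13, with 3 and 5 genes set at the floor), while Hoxd8 was higher. Across settings these medians ran from −9.461 to −2.881 and from −9.003 to −3.623. Of the trunk list, 8 of 12 were higher in WT and 7 of 12 in mdx5cv diaphragm (medians 1.58 and 1.46, with 2 at the floor in each, 0.8265 to 6.393 and 0.7873 to 1.99 across settings), while Tbx5 and Hoxc6 were lower.

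Matrix genes also differed between muscles. Mfap4, an elastic fibre protein, was 15.7-fold (13.9 to 17.8) higher in WT and 4.24-fold (4.10 to 4.38) higher in mdx5cv diaphragm, the collagen VI chain gene Col6a5 16.5-fold (10.1 to 28.9) and 25.3-fold (21.7 to 29.5), and Fbln1 3.94-fold (3.62 to 4.29) and 3.48-fold (3.31 to 3.67). The prostacyclin synthase Ptgis was 3.62-fold (3.11 to 4.23) and 26.0-fold (21.0 to 32.5) higher, the guidance cue Slit2 44.8-fold (15.3 to 218), from 3 UMIs in WT quadriceps, and 4.27-fold (3.56 to 5.16), and C1qtnf7 6.21-fold and 4.11-fold. S100a4, a calcium-binding protein of motile fibroblasts, was 10.5-fold (9.75 to 11.4) and 14.6-fold (13.7 to 15.6) lower in diaphragm, the BMP antagonist Chrdl1 20.3-fold and 8.77-fold, and the growth factor Ptn 27.0-fold (17.3 to 43.5) and 15.2-fold (13 to 17.8). Of the fibrillar and associated collagens, 3 of 13 were higher and 2 lower in WT diaphragm (median −0.21, −0.42 to 0.81, percentile 0.81), and 0 of 14 higher and 5 lower in mdx5cv diaphragm (median −0.49, −0.62 to −0.11, percentile 0.01), with Col6a3 lower in both. Across settings the WT median ran from −0.5046 under the stricter naming to 0.3237 among low-stress cells, and the mdx5cv median from −0.7318 to −0.3894. Of 15 basement membrane genes, 9 were lower and 0 higher in WT diaphragm (median −0.71, −0.77 to −0.29), and 2 were lower and 1 higher in mdx5cv diaphragm (median −0.27, −0.56 to 0.27). Matrix glycoproteins had medians of 0.30 and −0.03, with Fn1 2.31-fold and 2.92-fold lower in diaphragm and Postn 2.33-fold higher in WT and 1.74-fold lower in mdx5cv diaphragm. The Pi16 and Dpp4 list had medians of −1.60 (−1.77 to −0.22) and −0.40 (−0.96 to 0.24), the latter −0.8358 to 0.7484 across settings. TGF-beta genes had medians of 0.60 and 0.02, chemokines −0.10 and −0.29, complement −0.22 and −0.15, interferon genes −0.56 and −0.21, and adipogenic genes −0.18 and 0.06, in which the lipid transporters Cd36 and Apod were lower in diaphragm of both genotypes.

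Stress transcripts separated the WT libraries. All 17 immediate-early and dissociation stress genes were at least 1.5-fold higher in WT diaphragm than in WT quadriceps FAP-like cells, led by Atf3, 9.61-fold (8.24 to 11.3), Fos, 4.92-fold (4.69 to 5.16), and Btg2, 4.91-fold (4.41 to 5.48) (median 1.88, 1.36 to 2.16). In mdx5cv 4 were higher and 2 lower (median 0.37, 0.17 to 0.53). The heat-shock gene Hspb1, outside the list, was 4.95-fold (4.73 to 5.2) and 3.10-fold (2.95 to 3.27) higher in diaphragm. At weakest across settings its log2 ratios were 0.9448 in WT and 0.844 in mdx5cv. The list took a median of 2.36% of UMIs per WT diaphragm FAP-like cell, against 0.278% in WT quadriceps, 0.285% in mdx5cv quadriceps and 0.506% in mdx5cv diaphragm. Cell cycle genes were higher in WT diaphragm, 3 of 5 (median 0.63, 0.29 to 2.18), and lower in mdx5cv diaphragm, 13 of 14 (median −2.23, −2.43 to −1.95). Across settings the WT median ran from −0.1796 to 2.121 and the mdx5cv median from −3.198 to 0.1323, the last under the stricter naming.

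**Figure D4:**
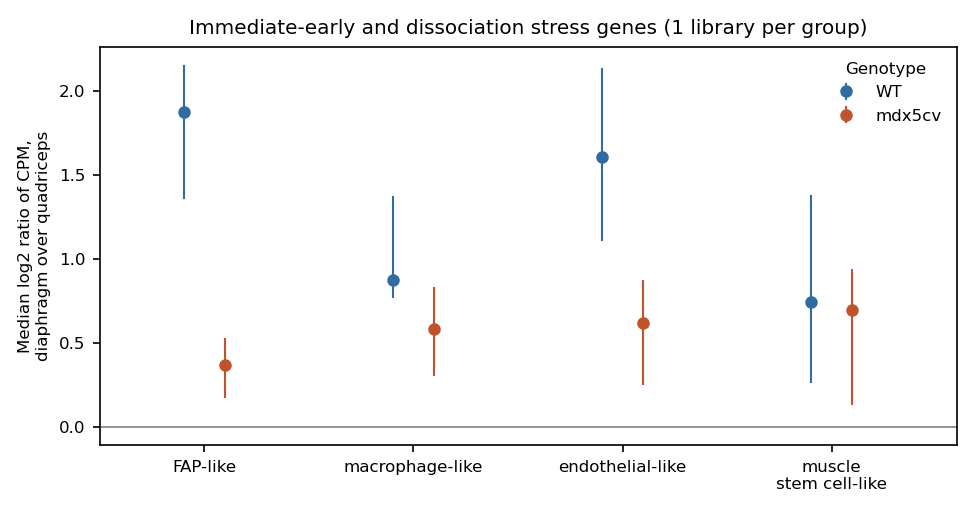
Median log2 ratio of CPM, diaphragm over quadriceps, of the immediate-early and dissociation stress list in 4 cell classes, with WT and mdx5cv as separate points and order-statistic intervals across list members as error bars. The WT medians were 1.88 in FAP-like, 0.87 in macrophage-like, 1.61 in endothelial-like and 0.75 in muscle stem cell-like cells.

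The genotype difference itself was set against muscle by subtracting the quadriceps log2 ratio from the diaphragm log2 ratio. Ptx3, a secreted pattern-recognition protein, was 71.4-fold (34.6 to 178) higher in mdx5cv quadriceps and 1.18-fold (1.05 to 1.32) higher in mdx5cv diaphragm, a difference of −5.92 (−7.00 to −4.84) on the log2 scale. Thbs4, a tendon-associated thrombospondin, was 41.4-fold (35.7 to 48.3) and 3.06-fold (3.02 to 3.11) higher (difference −3.76, −3.97 to −3.54), and C1qtnf3 159-fold (54.2 to 770) and 2.92-fold (2.71 to 3.16) (−5.76, −7.40 to −4.12). The mitotic gene Ube2c differed by −4.38 (−5.69 to −3.08) and the hyaluronan synthase Has1, higher in quadriceps and lower in diaphragm, by −3.51 (−3.92 to −3.10). In the other direction, Aldh1a3, a retinoic acid-synthesising enzyme, was 3.97-fold (3.39 to 4.66) lower in mdx5cv quadriceps and 6.21-fold (5.64 to 6.83) higher in mdx5cv diaphragm (difference 4.62, 4.36 to 4.89). The epithelial-type genes Krtdap and Dmkn were 85.4-fold (64.0 to 117) and 17.0-fold (13.1 to 22.3) lower in quadriceps and 3.09-fold and 1.08-fold lower in diaphragm. Il18r1, Tmem26 and the decoy receptor Il1r2 differed by 5.97, 4.32 and 3.6. By list, the median difference was −0.22 (−0.70 to 0.28) for collagens, −0.40 (−0.77 to −0.10) for collagen processing, 0.33 (0.06 to 0.53) for basement membrane, 0.34 (0.10 to 0.54) for interferon genes and 0.82 (0.06 to 1.19) for the Pi16 and Dpp4 list. It was −3.07 (−4.13 to −2.47) for cell cycle genes and −1.82 (−2.03 to −0.98) for stress genes, the latter moving with the stress transcripts of WT diaphragm. The cell cycle difference depended on the setting, since the diaphragm and quadriceps medians were 3.057 and 3.832 with principal components centred per library, where Ube2c differed by −0.6586, and 2.51 and 3.813 under the stricter naming. Among low-stress FAP-like cells the difference was 0.02333 for Has1 and 0.5103 for Tmem26. At their weakest across settings C1qtnf3 differed by −3.353, Ptx3 by −4.921, Thbs4 by −3.284, Il18r1 by 3.729, Il1r2 by 2.462 and Aldh1a3 by 4.162.

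Most UMIs of 41 collagens, glycoproteins and proteoglycans lay in FAP-like cells. These held 71.9% (71.7 to 72.1) of the 310923 such UMIs in named cells of WT quadriceps and 97.6% (97.57 to 97.61) of 2047200 in WT diaphragm. In the mdx5cv libraries they held 86.2% (86.17 to 86.29) of 1248712 UMIs in quadriceps and 96.5% (96.47 to 96.53) of 1728008 in diaphragm. The remainder lay mainly in endothelial-like (13.8%) and tenocyte-like cells (9.53%) in WT quadriceps, and in tenocyte-like (6.34%), muscle stem cell-like (2.72%) and macrophage-like cells (1.64%) in mdx5cv quadriceps. Matrix UMIs were 1.10% of muscle stem cell-like and 0.0819% of macrophage-like UMIs there. The estimated ambient share of all UMIs in mdx5cv quadriceps was 14.3% in muscle stem cell-like and 6.42% in macrophage-like cells. With the ambient profile subtracted, FAP-like cells held 88.28% of the matrix UMIs of that library. How much of the matrix UMIs of each other class came from outside the cell was not given separately. Matrix UMIs per FAP-like cell numbered 256, 326, 730 and 565 in WT quadriceps, WT diaphragm, mdx5cv quadriceps and mdx5cv diaphragm, and took 7.02%, 6.79%, 9.53% and 9.43% of the UMIs of the class. A tenocyte-like cell held 337 in WT and 665 in mdx5cv quadriceps. Shares follow the mix of cells recovered in each library, and RNA outside the recovered cells was not counted. The FAP markers Dcn, Lum, Col6a3, Col1a2 and Mfap5 are among the 41 genes. Clusters were named FAP-like partly by these transcripts, so the FAP-like share of matrix UMIs is partly set by the naming.

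Macrophage-like cells of both mdx5cv libraries carried more of most lipid-associated transcripts and less of several transcripts of resident macrophages. Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, was 258-fold (101 to 948) higher in mdx5cv quadriceps, from 4 UMIs in WT, and 753-fold (135 to 29750) higher in diaphragm, from 1 UMI. Spp1, encoding osteopontin, was 35.0-fold (27.3 to 45.7) and 211-fold (124 to 397) higher, the lipid carrier Fabp5 13.7-fold (11.8 to 15.9) and 23.5-fold (19.4 to 28.8), the lysosomal protease Ctsd 13.4-fold (11.9 to 15.1) and 9.15-fold (8.22 to 10.2), and the lipid receptor Trem2 6.58-fold (5.35 to 8.19) and 9.62-fold (7.22 to 13.1). Of the 17 lipid-associated genes, 15 were higher in quadriceps and 14 in diaphragm, 13 in both (medians 2.62, 1.72 to 3.74, and 2.10, 1.30 to 3.27; percentile 100 in both; 2 and 3 genes at the floor). Lpl and Mmp12 were higher in quadriceps and lower in diaphragm. Retnla, a marker of alternatively activated resident macrophages (chromosome 16, 48842551 to 48844461), was 58.5-fold (56.9 to 60.1) and 81.9-fold (77.1 to 87.1) lower, from 17785 and 9058 CPM in WT. The phagocytic receptor Timd4 was 72.0-fold (36.7 to 152) and 102-fold (51.0 to 230) lower, Lyve1 23.1-fold (18.7 to 28.5) and 49.1-fold (39.0 to 62.5), the scavenger receptor Cd163 16.1-fold (13.5 to 19.3) and 27.6-fold (22.4 to 34.2), and the lectin Cd209f 41.1-fold (31.3 to 54.4) and 159-fold (90.8 to 304). Of the resident list, 8 of 14 were lower and 2 higher in quadriceps and 11 of 15 lower and 2 higher in diaphragm (medians −0.65, −4.53 to 0.56, and −1.81, −4.79 to −0.52), Igf1 and Ccl8 being the genes higher in both. Across settings the resident medians ran from −1.343 to −0.3086 and from −2.505 to −1.043, and the lipid-associated median in quadriceps from 1.859 to 2.691. Lyz1, a lysozyme, was 38.0-fold (36.4 to 39.7) and 31.9-fold (29.7 to 34.2) lower, and Cd209g and Akr1c18 were lower in both muscles. Syngr1, Clec4d and Ly9 were higher in both. Ly6c2, a monocyte antigen, had 0 UMIs in both WT classes and was 24.7-fold and 36.0-fold higher in mdx5cv at the floor.

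Growth factors of macrophages were mostly higher in mdx5cv, 7 of 12 in quadriceps and 7 of 13 in diaphragm against 2 and 3 lower (medians 0.98 and 0.69), among them Osm, 3.18-fold (1.92 to 5.70) and 4.67-fold (2.90 to 8.05), Igf1, 2.15-fold (1.78 to 2.61) and 1.88-fold (1.54 to 2.32), and Tgfb1, 1.68-fold (1.43 to 2.0) and 1.61-fold (1.35 to 1.94). Fn1 was 4.51-fold and 4.59-fold lower. MHC class II genes were lower, 6 of 9 in each muscle (medians −0.87 and −0.71), including the invariant chain Cd74, 2.15-fold (2.12 to 2.18) and 1.64-fold (1.61 to 1.66). Inflammatory genes had medians of −0.25 (−0.96 to 1.58) in quadriceps (across settings −1.167 to 0.35) and −1.28 (−2.86 to −0.00) in diaphragm (−1.97 to −1.079). Il1b, an inflammatory cytokine, was 1.59-fold (1.14 to 2.29) higher in quadriceps and 3.36-fold (3.08 to 3.65) lower in diaphragm, and Ccl2 and Cxcl10 also went opposite ways. The stress list was lower in both muscles (medians −0.70 and −1.14). Among WT macrophage-like cells, diaphragm stood above quadriceps in the inflammatory list (median log2 ratio 2.75) and in the stress list (0.87). The diaphragm genotype medians of both lists are to be read against that WT library. Cell cycle genes had medians of 0.28 and 0.42 (across settings −0.423 to 0.617 and −1.944 to 0.6074), and genes of arrest and damage 0.56 and 0.84 (0.2323 to 1.035 in diaphragm). Scaling to the median ratio of abundant genes moved every macrophage log2 ratio by −0.10 in quadriceps and −0.12 in diaphragm, so values are to be read against those shifts. WT macrophage-like cells came mainly from clusters 1 and 19 (147 and 77 of 248 in quadriceps, 110 and 67 of 181 in diaphragm), and mdx5cv ones from clusters 1 and 6 (1913 and 748 of 3495, 838 and 493 of 1547), cluster 19 being led by Retnla and Lyz1 and cluster 6 by Spp1 and Gpnmb.

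Endothelial-like cells of both mdx5cv libraries carried more Col4a1 and Aplnr than those of the matching WT muscle. Col4a1, a basement membrane collagen, was 3.24-fold (3.09 to 3.4) higher in quadriceps and 3.29-fold (2.72 to 4.02) higher in diaphragm, and the apelin receptor Aplnr 3.02-fold (2.73 to 3.35) and 5.52-fold (2.96 to 11.6). Of 15 angiogenic genes, 7 were higher and 1 lower in quadriceps and 10 higher in diaphragm (medians 0.34, −0.12 to 1.70, and 0.72, 0.46 to 1.69, with 1 and 2 genes at the floor), Esm1 being lower in quadriceps and higher in diaphragm. Of the activation list, 7 of 11 were higher in quadriceps, including the venular glycoprotein Lrg1, 3.38-fold (2.80 to 4.07), and the leukocyte adhesion receptors Selp, 3.11-fold (2.21 to 4.35), and Icam1, 1.93-fold (1.51 to 2.46) (median 1.03, 0.19 to 1.64, and 0.2679 to 1.386 across settings). In diaphragm 3 of 10 were higher and Icam1 was 1.99-fold (1.39 to 2.80) lower (median 0.37, −0.59 to 1.08, with 4 genes at the floor). That median was −0.6413 with thinned cells, −0.5344 with the mean of per-cell CPM, −0.3129 with the highest doublet scores removed and 1.041 at a 50 CPM minimum, so no direction is read from it. Capillary lipid handling genes had medians of −0.35 and 0.50, with Car4 lower in quadriceps and higher in diaphragm. Cysltr1, a leukotriene receptor, was 5.65-fold (4.28 to 7.49) higher in quadriceps and 16.3-fold (2.84 to 650) higher in diaphragm, from 1 UMI in WT. The cytokine receptor Csf2rb was 16.4-fold (12.3 to 22.1) higher in quadriceps and 3.53-fold higher at the floor in diaphragm, where its log2 interval began at 1.474. Plec was 2.99-fold (2.59 to 3.45) and 9.08-fold (3.05 to 44.5) higher, Il4ra 4.70-fold (3.75 to 5.88) and 7.66-fold (2.05 to 64.3), and Rasa4 2.58-fold and 4.37-fold. The chaperones Hspa1a and Hsp90aa1, the immediate-early gene Jun and the detoxifying enzyme Gstp1 were between 2.09-fold and 4.81-fold lower, and the stress list had medians of −0.66 and −1.56. Cell cycle genes had medians of 1.03 and −0.17 (across settings −0.1205 to 2.707 and −4.432 to 0.4874), and genes of arrest and damage 0.08 and −0.43 (−0.821 to 0.2433 and −4.98 to −0.3596). Pcolce2, Cd248 and Scara5, which FAP-like cells also carry, were lower in both muscles, but the quadriceps direction depended on the setting. There Pcolce2 was at 1.306 with a mitochondrial limit of 5%, Cd248 at 0.205 with doublets kept, both at 0.5382 with the highest doublet scores removed, and Pcolce2, Cd248 and Scara5 at 0.4213, 0.4213 and 1.591 with principal components centred per library. Cluster 27, with 143 of 2683 WT quadriceps and 14 of 59 WT diaphragm endothelial-like cells, held endothelial together with mural and stem cell markers at 1.75 times the median UMIs. The diaphragm comparison rests on 59 WT cells with 175679 UMIs, and scaling to abundant genes moved its log2 ratios by −0.17. Matrix UMIs took 2.765% of endothelial-like UMIs in WT diaphragm and 0.7402% in mdx5cv diaphragm. The estimated ambient share of the WT diaphragm class was 9.64%, with an upper quartile of 61.2% across markers. The diaphragm values of Pcolce2, Cd248 and Scara5 are to be read against that background. With a mitochondrial limit of 5%, which left 2 WT cells, the diaphragm medians were −2.34 (angiogenic), −5.095 (activation) and −1.795 (capillary).

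In muscle stem cell-like cells of mdx5cv muscle, transcripts of quiescence took a smaller share of UMIs and those of commitment and division a larger. The class held 968772 UMIs in 462 WT and 3079489 in 305 mdx5cv quadriceps cells. In diaphragm it held 306080 in 131 WT and 1956131 in 249 mdx5cv cells. A lower share therefore need not mean fewer transcripts per cell. Chrdl2, a BMP antagonist, was 224-fold (75.5 to 1093) lower in quadriceps and 11.1-fold (7.26 to 17.1) lower in diaphragm, Spry1, a brake on growth factor signalling, 6.74-fold (6.01 to 7.57) and 5.70-fold (4.77 to 6.81), and Cd34 5.22-fold (4.14 to 6.60) and 4.09-fold (2.79 to 5.95). Of 13 quiescence genes, 10 were lower in quadriceps and 7 in diaphragm, with Col5a1 higher in both (medians −1.65, −2.75 to −0.28, and −1.31, −2.51 to 0.43). Pax7, the defining transcription factor of these cells, was 1.88-fold (1.63 to 2.17) lower in quadriceps and 1.28-fold (0.944 to 1.70) lower in diaphragm. Myog, which drives terminal differentiation, was 109-fold (55.3 to 253) higher in quadriceps and 4.73-fold (3.39 to 6.79) higher in diaphragm. The fusion gene Mymk was 59.6-fold higher in quadriceps, at the floor, and 3.89-fold (1.85 to 9.82) higher in diaphragm. Of the commitment list, 11 of 14 were higher in quadriceps and 8 of 12 in diaphragm (medians 4.82, −0.34 to 6.0, and 1.61, 0.45 to 1.96, with 5 and 2 genes at the floor), Des going opposite ways. Across settings the commitment medians ran from 1.686 to 5.248 and from 0.5315 to 1.801, the quiescence medians from −1.753 to −0.9083 and from −1.581 to −0.5618, and the cell cycle medians from 1.562 to 3.793 and from 0.5166 to 3.028. All 14 cell cycle genes were higher in each muscle (medians 3.51 and 2.92, with 2 and 10 at the floor). Genes of arrest and damage had medians of 1.75 and 0.37 (across settings 0.3853 to 1.871 and −1.342 to 0.5775), including Cdkn1c, 39.1-fold (24.7 to 66.2) and 3.59-fold (3.06 to 4.25) higher, and Cdkn1a, 9.43-fold higher in quadriceps and 2.53-fold lower in diaphragm. All 17 stress genes, of which the quiescence list shares Fos, were lower (medians −2.58 and −2.92, at weakest −1.585 and −1.859 across settings). Cluster 12 held 452 of 462 WT quadriceps and 128 of 131 WT diaphragm cells, and cluster 15 held 265 of 305 and 207 of 249 mdx5cv cells. Scaling to abundant genes moved log2 ratios by −0.11 in quadriceps and −0.27 in diaphragm. The estimated ambient share of this class was 4.17% in WT and 14.3% in mdx5cv quadriceps, and 0% and 4.91% in diaphragm. Matrix UMIs rose from 0.39% to 1.10% of its UMIs in quadriceps and from 0.279% to 0.726% in diaphragm. The collagen gene Col5a1 is to be read against that background.

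FAP-like cells clustered alone fell into 12 subclusters, 4 of which took at least 80% of their cells from 1 library, so library and cell state are not separated there. Of subcluster 0, led by Ces1d, Junb and Fos, 94.7% of 3737 cells were from WT diaphragm, and of subcluster 2, led by the tenocyte gene Tnmd and Sfrp4, 95.5% of 1657. Of subcluster 1, led by Col6a5, Fbln7 and Postn with the tenocyte marker Thbs4 among its top 10 genes, 93.6% of 2394 cells were from mdx5cv diaphragm, 76.0% of the FAP-like cells of that library. Subcluster 3, led by S100a4 and Hoxc10, held quadriceps cells of both genotypes. Subcluster 5, of 403 cells led by Timp1, Ccl2 and Inhba, came 77.7% from mdx5cv diaphragm. Subcluster 7 was led by the macrophage genes Cd74, Lyz2 and C1qb, and subcluster 10 by the endothelial genes Fabp4, Flt1 and Cdh5, as mixed droplets would be. Subcluster 8, led by Top2a, had a median of 14062 UMIs per cell.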

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

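The test that left out FAP-like cells with macrophage-marker UMIs was chosen only after the result was seen, as was the set of low-stress cells. None of the opposite directions between muscles or genotypes given here was tested, since each group had 1 library.

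Several results went opposite ways in the 2 muscles. Aldh1a3 in FAP-like cells had log2 ratios of mdx5cv over WT of −1.991 in quadriceps and 2.634 in diaphragm, Tmem26 of −1.584 and 2.734, Il1r2 of −2.212 and 1.389, and Has1 of 1.395 and −2.119. Among low-stress cells the difference between the muscles was 0.5103 for Tmem26 and 0.02333 for Has1. The endothelial-like share of cells had log2 ratios of −3.393 in quadriceps and 2.609 in diaphragm. The muscle stem cell-like share had −1.31 and 1.017. The cell cycle list of FAP-like cells had a median diaphragm over quadriceps log2 ratio of 0.6319 in WT and −2.231 in mdx5cv, the latter 0.1323 under the stricter class naming.

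The stress list stood higher in WT diaphragm than in WT quadriceps FAP-like cells, with a median log2 ratio of 1.878. Ambient RNA at its estimated share is argued against, because subtracting the ambient profile left 1.901. That share was 6.67% and 3.41% of FAP-like UMIs in WT quadriceps and WT diaphragm, so subtraction could change the ratio little. Handling of the whole library remains open: the lowest median in macrophage-like, endothelial-like and muscle stem cell-like cells was 0.7461, so the difference was shared by every class measured. A difference between the muscles themselves also remains open and was not tested.

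Collagen transcripts stood higher in mdx5cv FAP-like cells of both muscles, with a smaller median log2 ratio of 1.202. Weighting by deeper cells as the whole cause is argued against by 1.089 with every cell thinned to 1500 UMIs. Thinning keeps the expected proportions within a cell, so it could not test other effects of depth. Ambient RNA at its estimated share, at most 14.4% of FAP-like UMIs, is argued against by 1.23 after subtraction. With so small a share, subtraction could change the ratio little, so a larger ambient share was not tested. Stress of the WT diaphragm cells as the whole cause is argued against by 0.9256 among low-stress cells, of which WT diaphragm held 170. As a hypothesis, the higher collagen transcripts belong to the genotype, but animals and preparations also differed between libraries, and 1 library per group does not separate them. Libraries from several animals of each genotype would test it.

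Cell cycle transcripts stood higher in mdx5cv quadriceps FAP-like cells, with a median log2 ratio of 3.679. Weighting by deeper cells as the whole cause is argued against by 1.995 after thinning, which stayed above 0.5 times the value by little. Other effects of depth were not tested. Droplets shared with a proliferating macrophage remain open in part: in cluster 23, with 190 of these cells, macrophage markers reached a median of 0.1744 of their CPM in macrophage-like cells. As the whole cause they are argued against by 3.153 without the FAP-like cells that held 3 or more macrophage-marker UMIs. A genotype difference remains open and was not tested.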

How the results depend on the processing

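Chosen only after seeing the data were the alternatives that removed the highest doublet scores, named classes strictly, took low-stress FAP-like cells or left out FAP-like cells with macrophage-marker UMIs. No paired analysis was possible because each group had 1 library and the labels give no animal numbers. Over all results and settings, 303 of the values that answer a comparison stayed inside their interval, 77 moved outside it and 1 reversed. These counts do not number the changes of sign, since the interval of a list is the spread among its members. The diaphragm endothelial activation median of 0.373 stayed inside at −0.5344, and −0.6413 and −5.095 counted as moved, though each changed sign. For other lists the counts were 1889, 57 and 7, and for named genes 2205, 428 and 15. Among the 22 genes named for FAP-like genotype, strict naming weakened 11 in diaphragm and 1 in quadriceps by over 1.5 times, low-stress cells 8 and 4, thinned cells 2 and 12, and the mean of per-cell CPM 1 and 12. For FAP-like muscle, strict naming weakened 9 of 22 in mdx5cv and 2 in WT, and low-stress cells 6 and 12. Of the 16 macrophage-like genotype genes, thinning weakened 11 in quadriceps and 10 in diaphragm. Of the 16 endothelial-like genotype genes in diaphragm, thinning weakened 9, a minimum of 2000 UMIs 6 and the highest doublet scores removed 7 of the 13 measured. Of the 12 genes named for FAP-like genotype by muscle, thinning weakened 7, low-stress cells 6, strict naming 4 and the mean of per-cell CPM 4. For FAP-like genotype by muscle, Krtdap was at weakest 3.536 and Dmkn 3.318, and Ube2c −0.6586. Some lists gave no value at a 50 CPM minimum, where no member remained. The collagen medians of FAP-like genotype stayed between 1.24 and 1.57 in quadriceps and between 0.93 and 1.23 in diaphragm. Unless stated, the cause was not tested. Depth limits the WT quadriceps library, with a median of 2055 UMIs, and the 59 WT diaphragm endothelial-like cells. Percentages below are FAP-like shares, macrophage-like shares and the share of matrix UMIs in FAP-like cells.

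With 500 UMIs and 300 genes, FAP-like cells were 15.33% of WT quadriceps, macrophage-like cells 41.29% of mdx5cv quadriceps, and the matrix share 69.74% in WT and 86.39% in mdx5cv quadriceps. With 2000 UMIs and 1000 genes, FAP-like shares were 30.64% (WT quadriceps), 87.28% (WT diaphragm), 20.13% (mdx5cv quadriceps) and 44.94% (mdx5cv diaphragm). Macrophage-like shares were 7.742% in WT quadriceps, 45.92% in mdx5cv quadriceps and 23.76% in mdx5cv diaphragm, matrix shares 72.09%, 97.21%, 85.72% and 96.12%, and the endothelial capillary median in diaphragm 0.8623.

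With a mitochondrial limit of 5%, FAP-like shares were 33.97%, 88.43%, 23.81% and 47.4%, macrophage-like shares 9.347% in WT and 33.62% in mdx5cv quadriceps, and matrix shares 84.0%, 98.12%, 92.76% and 96.15%. The diaphragm endothelial medians were −5.095 (activation), −1.795 (capillary) and −2.34 (angiogenic), and log2 ratios there were −3.68 for Cysltr1, −4.432 for Csf2rb, −2.323 for Aplnr, −3.395 for Lrg1, −3.188 for Plec, −3.471 for Rasa4 and −4.036 for Il4ra, because 2 WT cells remained. Pcolce2 in quadriceps was at 1.306, and the stress list of muscle stem cell-like cells, diaphragm over quadriceps in mdx5cv, at −0.499.

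With the highest doublet scores removed, FAP-like shares were 18.95% in WT quadriceps and 82.63% in WT diaphragm, macrophage-like shares 40.16% and 20.25% in mdx5cv quadriceps and diaphragm, and matrix shares 77.39%, 97.91%, 86.89% and 96.77%. The FAP-like cell cycle median in diaphragm was −0.5234, the endothelial angiogenic median in diaphragm 0.3031, and Pcolce2 and Cd248 in quadriceps endothelial-like cells 0.5382 and 0.5382. With doublets kept, the FAP-like share of mdx5cv quadriceps was 19.25%, matrix shares were 70.58%, 97.7%, 85.64% and 95.23%, and Cd248 was at 0.205.

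With components centred per library, the FAP-like share of WT quadriceps was 19.29%, macrophage-like shares 6.804%, 3.486%, 50.7% and 26.19%, and matrix shares 76.79%, 95.55%, 87.32% and 95.94%. The FAP-like cell cycle median of diaphragm over quadriceps in WT was −0.1796, and in quadriceps endothelial-like cells Pcolce2 was at 0.4213, Cd248 at 0.4213 and Scara5 at 1.591. With strict naming, FAP-like shares were 58.48% in WT diaphragm, 15.58% in mdx5cv quadriceps and 5.766% in mdx5cv diaphragm, macrophage-like shares 39.48% and 20.39% in mdx5cv quadriceps and diaphragm, and matrix shares 71.59%, 96.23%, 85.04% and 75.66%, because whole clusters lost their names. The collagen medians of diaphragm over quadriceps were −0.5046 in WT and −0.7318 in mdx5cv, and the cell cycle median in mdx5cv was 0.1323.

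With Leiden resolution 0.5, macrophage-like shares were 3.524%, 1.53%, 36.89% and 19.25%, and matrix shares 71.33%, 97.24%, 86.71% and 96.42%. With ambient RNA subtracted, matrix shares were 74.21%, 97.93%, 88.28% and 97.29%, and with resolution 2.0 the matrix share of mdx5cv diaphragm was 96.38%. Among low-stress FAP-like cells, which were selected on the list itself, the stress medians were 0.5485 (genotype, quadriceps) and −0.2166 (muscle, mdx5cv), the cell cycle median −0.4816 (genotype, diaphragm), and Has1, genotype by muscle, 0.02333. With thinned cells the endothelial activation median in diaphragm was −0.6413. At subcluster resolution 1.0 there were 20 FAP-like subclusters.

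Other list medians moved by over 1.5 times under at least 1 setting, with these ranges across settings. For FAP-like genotype they were −3.041 to −1.93 (Pi16 and Dpp4, quadriceps), −1.956 to −0.5992 (the same, diaphragm), −0.7918 to 0.08034 (trophic, quadriceps), 0.148 to 1.573 (hindlimb, diaphragm), −0.9586 to 0.204 (trunk, diaphragm), −0.8653 to 0.5485 and −2.191 to −0.23 (stress, quadriceps and diaphragm), 1.995 to 3.874 (cell cycle, quadriceps), −1.055 to 0.2524 (arrest, diaphragm) and −0.7394 to 0.1158 (dystrophin complex, quadriceps). For FAP-like muscle they were −0.2975 to 0.5028 (myofibroblast, mdx5cv), 0.6239 to 2.016 and −0.2166 to 1.237 (stress, WT and mdx5cv) and −0.6345 to 0.04837 (dystrophin complex, WT). The dystrophin complex medians of genotype ran from −0.5057 to 0.3281 in macrophage-like quadriceps, −3.726 to 0.6514 in endothelial-like diaphragm and −1.269 to 0.09381 in muscle stem cell-like diaphragm cells. The endothelial stress median of muscle in mdx5cv ran from 0.3762 to 1.221 and the diaphragm activation median of genotype from −5.095 to 1.041. Smaller medians changed sign too. For genotype these ran from −0.2118 to 0.4039 (chemokines, FAP-like diaphragm), −0.411 to 0.5573 (adipogenic, the same), −0.385 to 0.126 (trophic, the same), −0.6186 to 0.3383 (dystrophin complex, macrophage-like diaphragm) and −0.05618 to 0.5938 (dystrophin complex, muscle stem cell-like quadriceps). For FAP-like muscle they ran from −0.0599 to 0.5941 (matrix glycoproteins, WT), −0.1609 to 0.3326 (matrix proteases, WT) and −0.3819 to 0.2174 (complement, mdx5cv). The other list medians that changed sign stood between −0.1946 and 0.1431.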

Other observations

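A neighbouring pair of nuclear body genes was almost absent from the mdx5cv libraries. Sp110 (chromosome 1, 85576899 to 85598817, minus strand, GRCm38) had 676 and 911 UMIs in the WT quadriceps and WT diaphragm libraries and 7 and 22 in the mdx5cv ones. Sp140 (85600378 to 85645037, plus strand) had 333 and 782 against 36 and 30. The next gene, Sp100 (85649988 to 85709998, plus strand), chosen after its values were seen, had 2871, 2136, 10041 and 5449 UMIs, or 152, 53.1, 160 and 110 CPM. Counts of 3' tags do not tell a loss of transcript from a strain difference in sequence at this locus, which was not analysed here, so the ratios are not read as changes of expression. In FAP-like cells Sp110 was lower in mdx5cv quadriceps, with 2 UMIs, and 120-fold lower at the floor in mdx5cv diaphragm, with 0 UMIs. In endothelial-like cells it was 21.3-fold and 17.6-fold lower at the floor. The WT diaphragm value there rests on 10 UMIs, at 56.92 CPM (27.3 to 104.7). In macrophage-like cells Sp140 was 85.0-fold (46.4 to 166) and 133-fold (48.9 to 509) lower.

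Stress genes set the WT muscles apart in other classes too. The list's median diaphragm over quadriceps log2 ratio in WT was 0.87 (0.77 to 1.38) in macrophage-like, 1.61 (1.11 to 2.14) in endothelial-like and 0.75 (0.26 to 1.38) in muscle stem cell-like cells, and in mdx5cv 0.58, 0.62 and 0.69. Inflammatory genes of macrophage-like cells were higher in diaphragm, 13 of 14 in WT (median 2.75, 1.59 to 3.71, with 3 genes at the floor, 0.8789 to 2.881 across settings) and 10 of 13 in mdx5cv (median 0.78, 0.28 to 1.27).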
